A study of Mus musculus with 6 samples.

How the data were processed

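The data are gene counts of 6 bulk RNA sequencing libraries from sorted mouse CD4 T cells, 2 each of HD Tfh, LD Tfh and naive cells. Tfh cells were sorted by CD4, CD44, PD-1 and CXCR5 and against FOXP3, Ly6C and CD162, and naive cells by CD4 and low CD44 and against FOXP3, among other markers, per the labels. RNA was isolated with a micro column kit and made into Illumina libraries, per the labels' protocols. The deposited table holds whole-number counts per gene, not normalized, which the values bear out: totals differ between libraries. The submitters' processing notes name STAR, featureCounts, limma and the mouse build GRCm38, with no versions or roles. The deposited table is named as reverse-stranded counts, so strand was used in counting. The annotation release is not given in the sources used here, and counts of close paralogs (Ly6c1 and Ly6c2, Hba-a1 and Hba-a2, the Bcl2a1 family, immunoglobulin genes) are uncertain.

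The table lists 46078 genes with 45 biotype labels, 20395 labelled protein coding and 25683 labelled otherwise, and all were used. Some labels are those of a transcript: 1867 genes labelled otherwise are protein coding in release vM21, and 329 labelled protein coding are of another type there. Non-coding RNAs were therefore taken by their type in that release. Of the identifiers, 45143 were found in a GRCm38 annotation (release vM21), from which coordinates were taken, and all 14862 tested genes found there lay on the same chromosome in both. Groups were taken from the labels. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of 26.7 for LD, 25.0 for HD and 48.4 for naive), so none was counted as a duplicate. The first principal component of log2 CPM (counts scaled by effective library size) (prior count 2) held 62.1% of the variance and the second 26.8%.

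The tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Counts were filtered with edgeR's filterByExpr, which left 14923 genes, scaled by TMM and fitted in a single quasi-likelihood model over all 6 libraries with 3 residual degrees of freedom (edgeR 4.0.16, R 4.3.3, robust estimates; common biological coefficient of variation 15.3%). Each comparison was tested with edgeR's two-sided quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2, with standard errors from the F statistic. A group with 0 counts was given a floor of 3 counts over the group, which makes a fold a lower bound. Such floors cover counting error only, and the bootstrap interval given below covers the resampling of genes only. The depth makes 1 count worth 0.0199 to 0.0317 CPM, and floors per library lie between 0.0597 and 0.0952 CPM.

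For 26 gene lists with 640 entries (639 found) the members that passed were counted over all genes and adjusted over the list alone. The lists cover sort genes, the Tfh programme, naive and resting genes, Th1, Th2, Th17 and regulatory T cells, inhibitory receptors with chronic stimulation, type I interferon and interferon gamma responses, G2 and mitosis, replication, immediate early and heat shock genes, mitochondrially encoded genes, ribosomal proteins, glycolysis, the nuclear respiratory chain, cholesterol synthesis, apoptosis, homing, and 6 lists of other cells (B cells, germinal centre B and plasma cells, myeloid cells, CD8 and natural killer cells, stroma, red cells). Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and called at an adjusted p under 0.05. Camera compares a list with all other genes. Camera called 9 lists (5 higher) for HD against LD, 19 (16 higher) for HD against naive and 16 (13 higher) for LD against naive. With an estimated correlation the B cell list of HD against LD held its call, and no other call held. Fry, which asks whether a list's genes move on balance in a single direction and compares with no other genes, called 6, 21 and 16 lists.

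Named genes were chosen by rule in each comparison: up to 10 higher and 10 lower genes with the largest fold change among those that passed, with no overlap between the libraries of the groups and a mean of at least 10 CPM in the higher group; the sort genes; Bcl6, Tbx21, Gata3, Foxp3, Ifng, Il4, Il13 and Il21; and up to 4 members of each list with the smallest adjusted p. Genes named outside the rule are said to be chosen after their values were seen, or are per-library examples for other cell types. Il13 was below the count filter and was not tested. Some genes chosen by the rule are not reported.

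Overlap between the comparisons with naive cells was set beside independent lists and 20 simulations of unchanged groups drawn from the naive means and fitted dispersions. Alternatives were DESeq2 (1.42.0), limma-voom, RLE scaling, no filter and a filter of 50 counts in each library of a group, only the groups compared, the replicate number as a block, and each library left out in turn. Added after seeing the data were only genes labelled protein coding (which leaves out coding genes with another label), a run without 792 genes of chromosomes X and Y, immunoglobulins and the lists of other cells, per-library loess corrections (span 0.5) for purine share and for GC content and length of the longest transcript of a gene, and counts thinned to the smallest library.

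The steps were tested on simulated data with 200 changed genes, drawn from genes with a mean of at least 10 CPM in the groups compared. For HD against LD (14479 genes) 96% of 2-fold and 100% of 4-fold changes were recovered with 9 false calls, for HD against naive (14274 genes) 93% and 100% with 16, and for LD against naive (13893 genes) 97% and 99% with 13. A shifted list was called in each comparison (14467, 14247 and 13889 genes) by camera, by camera with an estimated correlation and by fry, with 0 other lists called. Genes were drawn independently in these simulations, so they could not show false list calls that come from correlation between genes. With a simulated purine trend the correction lowered false calls from 891 to 20 (HD against LD, 14495 genes), from 803 to 15 (HD against naive, 14261 genes) and from 1049 to 18 (LD against naive, 13897 genes).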

Results

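RNA sequencing counts of 6 mouse libraries were analysed, in 3 groups of 2. Follicular helper T (Tfh) cells, the CD4 T cells that help B cells in germinal centres, were sorted from mesenteric lymph nodes of FIR mice at day 21 after infection with the whipworm Trichuris muris. The high dose (HD) group had received 200 eggs, which the labels call acute infection, and the low dose (LD) group 30 eggs, which they call chronic. The background group held naive CD4 T cells of uninfected mice. Total counts were 36468537 and 29711202 in the LD libraries, 47901405 and 40408625 in the HD libraries, and 46157446 and 47202343 in the naive libraries. Levels are in CPM (counts scaled to library size), as mean ± SD of the 2 libraries of a group, and each adjusted p beside a gene comes from edgeR. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Libraries of the same group correlated at 0.98 to 0.985 across genes (Pearson, log2 CPM; genes are not independent replicates). Of the genes named in the text as higher or lower, each had both libraries of the higher group above both libraries of the lower group.

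The comparison of HD with LD Tfh cells asks how Tfh cells of acute and of chronic worm infection differ. Genes of cell division were lower in HD Tfh cells. Ccnb2, a mitotic cyclin, stood at 42.3 ± 2.85 CPM in HD and 85.1 ± 0.599 CPM in LD (log2 fold change -1.01, SE 0.12, adjusted p = 0.00016). Receptors for interleukins 18 and 33 were lower as well: Il18r1 stood at 36.3 ± 0.605 against 125 ± 38.5 CPM (log2 fold change -1.79, SE 0.18, adjusted p = 0.000118) and Il1rl1, the receptor for interleukin 33, at 7.66 ± 0.972 against 25.8 ± 9.61 CPM (log2 fold change -1.75, SE 0.26, adjusted p = 0.00075). Genes of B cells, plasma cells and myeloid cells were far higher in the HD libraries, with the B cell surface gene Ms4a1 at 244 ± 15.8 against 4.28 ± 0.546 CPM (log2 fold change 5.84, SE 0.14, adjusted p = 3.71e-10). In all, 3276 of 14923 genes tested changed, 1838 higher and 1438 lower in HD.

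Of the 35 genes on the list for G2 and mitosis, 31 fell, 0 rose and 4 did not pass (33 lower adjusted over the list alone). The median log2 fold change was -0.92 (camera adjusted p = 1.83e-17, and adjusted p = 0.166 with an estimated correlation). Hmgb2, a chromatin protein of dividing cells, stood at 116 ± 4.95 against 286 ± 17.6 CPM (log2 fold change -1.30), and Ndc80, a kinetochore protein, at 8.0 ± 1.42 against 22.4 ± 1.09 CPM (log2 fold change -1.48). Of the 37 genes for DNA replication, 22 fell and 15 did not pass (26 lower adjusted over the list alone). Their median was -0.53 (camera adjusted p = 1.23e-08, and adjusted p = 0.601 with an estimated correlation). The call ended with fry, which tests a list without other genes (adjusted p = 0.0795). Rrm2, a subunit of ribonucleotide reductase, stood at 70.0 ± 2.04 against 142 ± 33.4 CPM, and Pcna, the sliding clamp of DNA polymerase, at 178 ± 1.68 against 299 ± 37.2 CPM. In the same libraries 13 T cell genes chosen after their values were seen had log2 fold changes from -0.31 to 0.13, with a median of -0.19. Of these, Zap70 (-0.31, adjusted p = 0.0384) and Cd3g (-0.30, adjusted p = 0.0456) fell.

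**Figure D1:**
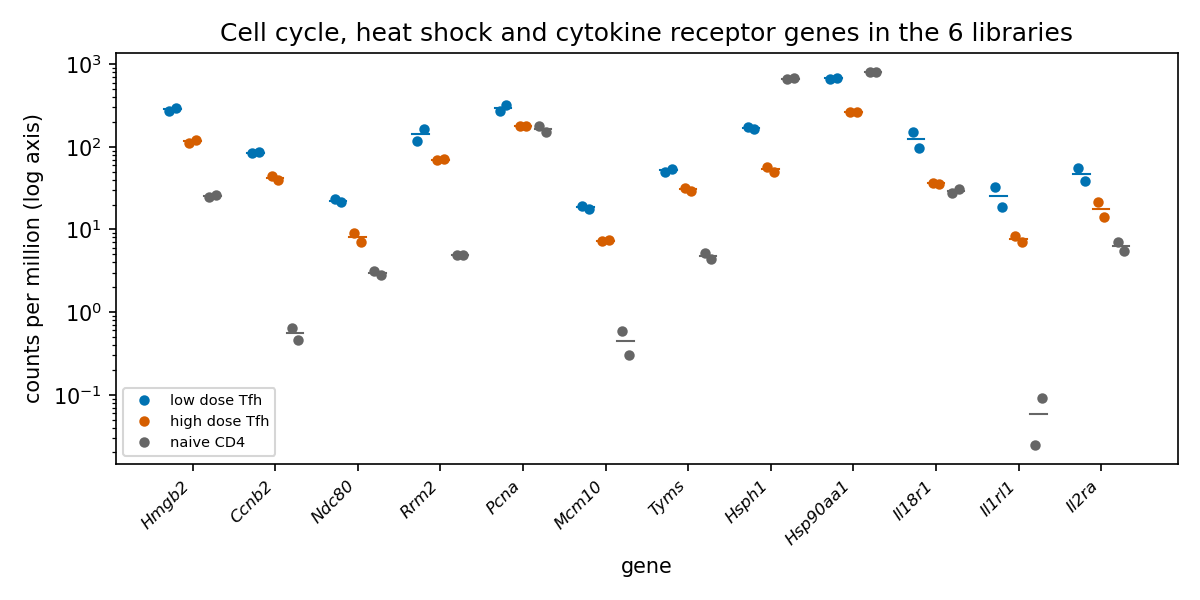
Level of 12 genes of the cell cycle, heat shock and cytokine receptors in each library, in CPM on a log axis, by group; dots are libraries and short lines group means of 2. Ccnb2 lay at 42.3 CPM in HD Tfh cells, 85.1 CPM in LD Tfh cells and 0.551 CPM in naive cells.

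Heat shock and immediate early genes moved both ways. Of 34 genes, 10 fell and 6 rose (14 and 8 adjusted over the list alone, camera adjusted p = 0.0118, lower, and adjusted p = 0.569 with an estimated correlation). The chaperones Hsph1 (53.3 ± 4.60 against 169 ± 8.52 CPM, log2 fold change -1.67) and Hsp90aa1 (265 ± 4.11 against 674 ± 13.9 CPM, -1.35) fell, as did Jun (-1.64) and Dusp1 (-1.28), while Egr3 rose (1.45). The call of this list ended without LD replicate 1 (adjusted p = 0.209), without HD replicate 2 (adjusted p = 0.085) and with fry (adjusted p = 0.126). Of 40 type I interferon response genes, 8 fell and 32 did not pass (8 lower adjusted over the list alone). Their median was -0.30 (camera adjusted p = 0.000643, and adjusted p = 0.948 with an estimated correlation). Usp18, a brake on interferon signalling, stood at 51.7 ± 7.54 against 86.3 ± 5.36 CPM, and Xaf1 at 43.8 ± 5.38 against 74.9 ± 11.5 CPM. This call ended without LD replicate 1 (adjusted p = 0.0542) and with fry (adjusted p = 0.307).

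The sorted markers differed little. PD-1 (Pdcd1) stood at 185 ± 11.8 against 226 ± 24.5 CPM, Cxcr5 at 622 ± 84.0 against 586 ± 74.9 CPM and Cd4 at 1407 ± 102 against 1540 ± 45.1 CPM, and none of these passed. Pdcd1 passed without LD replicate 1 (adjusted p = 0.0479). Of the 9 sort genes 1 rose and 8 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.71). On the Tfh list, 6 of 30 genes rose and 3 fell (10 and 3 adjusted over the list alone), and camera did not call it (adjusted p = 0.239). Pou2af1, a transcriptional coactivator found in B cells and Tfh cells, rose (256 ± 3.94 against 88.7 ± 8.90 CPM, 1.53), as did Cxcr4 (0.68) and Izumo1r (0.66), both smaller after the purine correction given below, while the costimulator Icos fell (659 ± 6.95 against 1105 ± 94.8 CPM, -0.75). The Tfh regulator Bcl6 stood at 120 ± 2.03 against 83.1 ± 17.7 CPM (adjusted p = 0.0686). It passed without LD replicate 2 (adjusted p = 0.0129), naive replicate 1 (0.0216) or naive replicate 2 (0.0211). It also passed with DESeq2 (adjusted p = 0.0297), limma-voom (0.0319), only these 2 groups (0.0235) or no filter (0.000128). Bcl6 passed as well with the replicate number as a block (edgeR adjusted p = 0.0135) or no X, Y, immunoglobulin and other cell genes (0.0492). After the purine correction it did not pass (0.46, edgeR adjusted p = 0.114). Of 24 naive and resting T cell genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.492), among them Ccr7, a lymph node homing receptor (0.63, and adjusted p = 0.0527 without HD replicate 1).

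Lineage genes of helper T cells moved in opposite ways within their lists. Tbx21, which encodes the Th1 factor T-bet, stood at 46.0 ± 1.0 against 67.2 ± 0.0593 CPM (log2 fold change -0.55, SE 0.11, adjusted p = 0.00545; 0.0535 without HD replicate 1 and 0.0507 without HD replicate 2). Gata3, the Th2 factor, stood at 55.5 ± 5.15 against 75.6 ± 10.9 CPM (log2 fold change -0.45, SE 0.13, adjusted p = 0.025; 0.178 without LD replicate 2 and 0.225 without HD replicate 2). Ifng, Il4 and Il21, cytokines of helper T cells, did not pass, with log2 fold changes of -0.33, 0.20 and -0.19, although Ifng passed without LD replicate 2 (-0.81, adjusted p = 0.0133) and stood at 0.40 without LD replicate 1 (adjusted p = 0.219). Foxp3 (-0.63, and 0.02 without LD replicate 1) did not pass, at 1.15 CPM in HD and 1.78 CPM in LD. Without HD replicate 1, Il4 stood at -0.29 and Il21 at 0.05. Of 28 Th1 genes 1 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.433). Of 16 Th2 genes 2 rose, including the interleukin 4 receptor Il4ra (138 ± 5.92 against 65.9 ± 16.6 CPM, 1.06), and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.795). Of 13 Th17 genes 3 rose, including Cd83 (1.5), and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.239). Of 17 regulatory T cell genes Capg rose (0.81) and 2 fell, including the interleukin 2 receptor Il2ra (17.8 ± 4.98 against 47.1 ± 12.5 CPM, -1.41) (1 and 2 adjusted over the list alone, camera adjusted p = 0.587). Of 20 inhibitory receptor and chronic stimulation genes 5 rose, including Lag3 (321 ± 26.4 against 166 ± 9.59 CPM, 0.95), and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.37). Genes of B and myeloid cells were far higher in the same HD libraries, as given below. Which cells gave the rises on these helper T cell lists and the Tfh list, such as Il4ra, Cd83, Capg and Pou2af1, was not tested. Nor was the source of the higher mean of Bcl6 in the HD libraries.

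The list of 35 interferon gamma response genes held 7 that rose and 6 that fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.607). Those that rose included Ciita (5.04) and Cxcl9 (6.01), which antigen-presenting cells express, and Tap1 (0.71), and those that fell included the guanylate-binding protein gene Gbp8 (-1.06). Ribosomal proteins went both ways, with 9 of 61 higher and 13 lower (11 and 13 adjusted over the list alone, camera adjusted p = 0.433), such as Rplp2 (0.85) and Rpl14 (-0.69). Of 55 nuclear respiratory chain genes 7 rose, such as Cox8a (0.94), and 6 fell, such as Ndufb3 (-0.74) (8 and 7 adjusted over the list alone, camera adjusted p = 0.981). Of 13 mitochondrially encoded genes mt-Co1 rose (0.44) and 3 fell, mt-Co2 (-2.12), mt-Atp6 (-2.15) and mt-Co3 (-1.67), likewise adjusted over the list alone (camera adjusted p = 0.217). The 3 that fell were counted at 2.48 to 13.1 CPM, against 17468 or more for mt-Co1, and share near-identical nuclear copies, so their values are uncertain. The call of mt-Co1 ended without LD replicate 2 (adjusted p = 0.174) and without HD replicate 2 (0.124), and after the purine correction (0.12, adjusted p = 0.508), under which the list was called lower (adjusted p = 1.9e-05). Of 20 glycolysis genes 1 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.607). Of 23 cholesterol synthesis genes 1 rose (0 adjusted over the list alone, camera adjusted p = 0.913). Of 21 apoptosis and survival genes 1 rose and 3 fell, including the caspase gene Casp8 (-0.59) (0 and 3 adjusted over the list alone, camera adjusted p = 0.433). Of 28 homing and adhesion genes 5 rose, including Ccr1 (5.25), a receptor found on myeloid cells, and 3 fell, including Ccr4 (-0.66, and adjusted p = 0.107 without HD replicate 2) (5 and 4 adjusted over the list alone, camera adjusted p = 0.433). For the Th1, Th2, interferon gamma, glycolysis, respiratory chain, cholesterol and apoptosis lists, median, mean and test differed in sign.

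Genes of other cell types separated HD from LD libraries. All 20 measured B cell genes rose, also adjusted over the list alone. The median log2 fold change was 5.76 (camera adjusted p = 1.22e-116, and adjusted p = 0.0201 with an estimated correlation). The B cell transcription factor Spib stood at 81.3 ± 4.93 against 0.313 ± 0.218 CPM. Of 14 germinal centre B and plasma cell genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 3.65, or 3.26 with genes at 0 counts set at their bound (camera adjusted p = 7.9e-16, and adjusted p = 0.0816 with an estimated correlation). Mzb1, a plasma cell gene, stood at 75.5 ± 7.10 against 0.359 ± 0.373 CPM. Of 24 myeloid and dendritic cell genes 20 rose (21 adjusted over the list alone), with a median of 5.12, or 4.51 with genes at their bound (camera adjusted p = 6.74e-25, and adjusted p = 0.0816 with an estimated correlation), among them Csf1r, the receptor for a macrophage growth factor (7.53 ± 0.758 against 0.0519 ± 0.0734 CPM). Of 15 genes of CD8 T and natural killer cells 5 rose (6 adjusted over the list alone). Their median was 1.26 (camera adjusted p = 0.000879, and adjusted p = 0.166 with an estimated correlation). Those that rose included Cd8a (16.5 ± 0.396 against 0.160 ± 0.0429 CPM). Of 8 stromal and endothelial genes 0 rose or fell by edgeR, also adjusted over the list alone (camera adjusted p = 0.71). Of the 1838 genes higher in HD, 539 had means under 1 CPM in both LD and naive cells, and 148 of these were immunoglobulin genes.

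**Figure D2:**
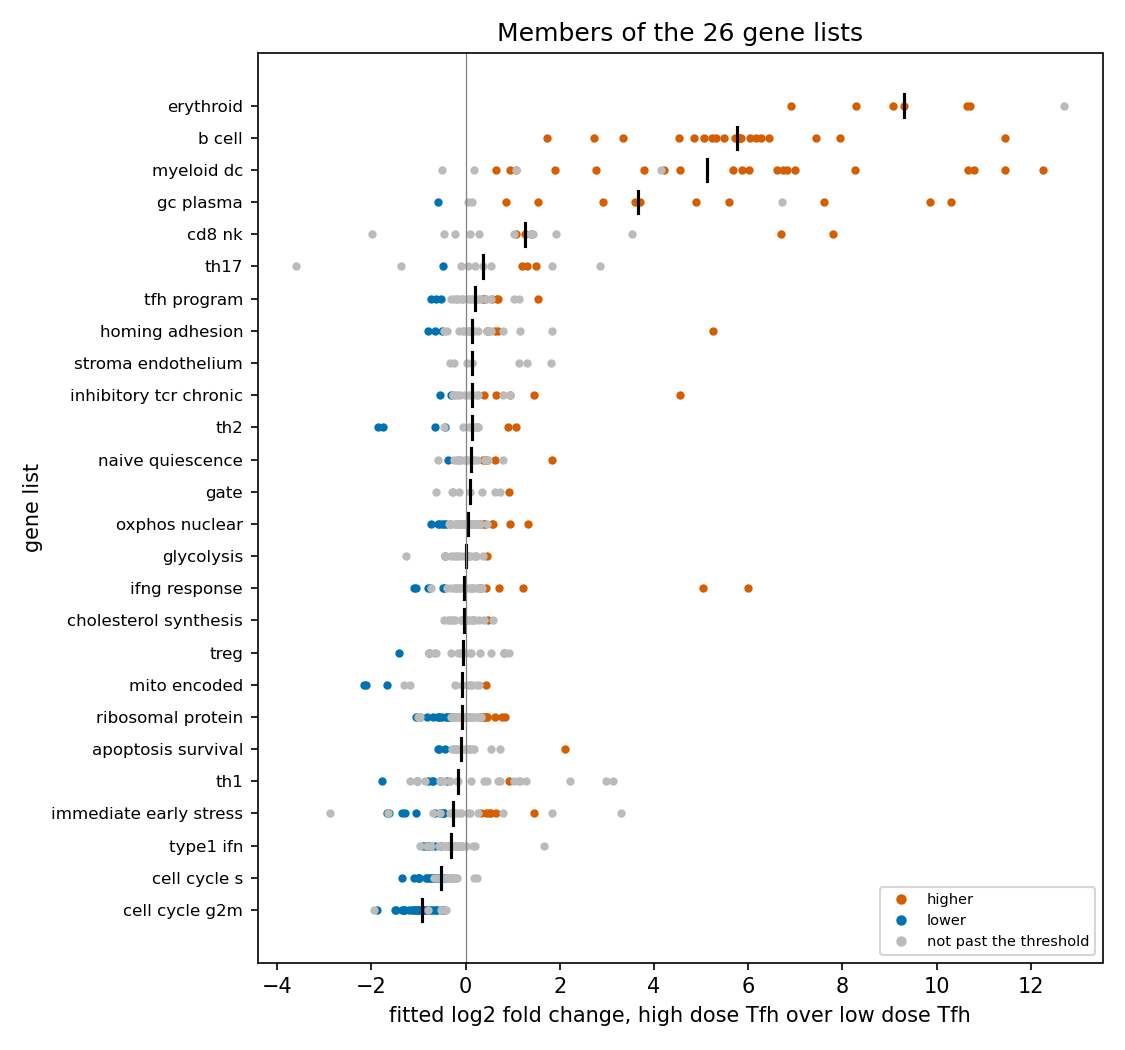
Fitted log2 fold change of HD over LD Tfh cells (horizontal axis) for each measured member of the 26 gene lists; a black bar marks the list median, and members at 0 counts in a group are drawn at a fitted value that is no bound. Medians ran from -0.92 for G2 and mitosis to 5.76 for B cells and 9.30 for red cell genes.

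The 10 genes with the largest rises under the naming rule were of the same kind or lay on the Y chromosome. Against 0 counts in both LD libraries, the immunoglobulin gene Ighg2c was at least 4543-fold higher in HD, and the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at least 1686-, 1420-, 1107- and 1073-fold higher. Igkv14-111 (at least 579-fold), Ccl22 (361-fold), Plbd1 (349-fold), Igkv4-72 (326-fold) and Tgfbi (245-fold) followed, each as a lower bound set by a floor of 3 counts over the group. The call of Igkv4-72 ended without LD replicate 1 (adjusted p = 0.0512) and without LD replicate 2 (adjusted p = 0.051). Xist, which silences the inactive X chromosome, held 3414 and 2563 counts in the LD libraries, 0 and 10 in HD and 0 and 0 in naive. The other large falls were Malat1, a nuclear non-coding RNA (105 ± 22.2 against 1132 ± 179 CPM, log2 fold change -3.43), Gpt2 (-2.59), Hmgn5 (-2.10), Zc3h13 (-2.04), Slfn10-ps (-2.0) and the mitochondrial and receptor genes above. Of 7 red cell genes 6 rose (7 adjusted over the list alone; median 9.30, or 6.88 with genes at their bound, camera adjusted p = 1.14e-10, and adjusted p = 0.166 with an estimated correlation). Hbb-bs held 0 and 0 counts in LD, 839 and 1017 in HD, and 906 and 232 in naive libraries.

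**Figure D3:**
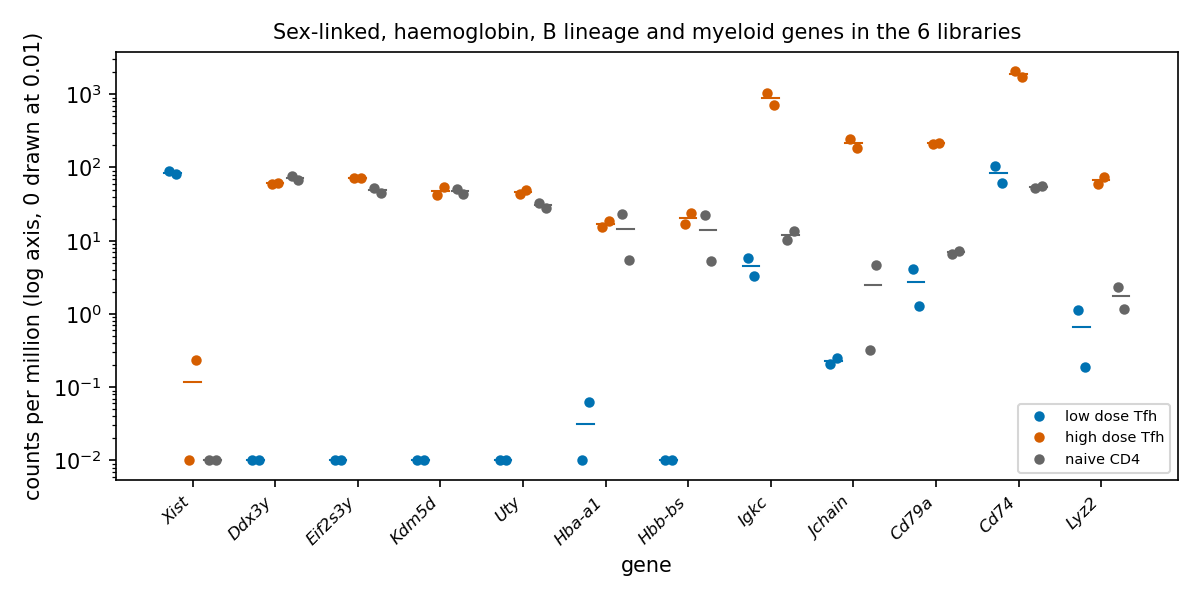
Level of sex-linked, haemoglobin, B lineage and myeloid genes in each of the 6 libraries, in CPM on a log axis with 0 drawn at 0.01; dots are libraries and short lines group means. The 4 Y-linked genes were at 0 in both LD libraries and between 28.4 and 76.3 CPM in the other 4.

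The fold change of HD over LD also fell with the share of purines (A and G) in the transcript. Across 7136 genes labelled protein coding in the table with a mean of at least 10 CPM, Spearman's correlation was -0.507, where genes are not independent replicates, and median log2 fold changes ran from 0.27 in the tenth of genes with the lowest share to -0.41 in the highest. After a correction for this share, chosen after seeing the data, 2444 genes changed, 1573 higher and 871 lower in HD. In this run 22 of the 35 G2 and mitosis genes (21 of the 31 above), 15 of the 37 replication genes (14 of the 22 above) and 4 of the 40 type I interferon genes (all among the 8 above) fell. The 3 lists kept their calls, with medians of -0.82 (camera adjusted p = 5.57e-16), -0.39 (3.03e-08) and -0.25 (0.00478). Ccnb2 (-1.01 to -0.99), Hmgb2 (-1.30 to -1.12), Rrm2 (-1.02 to -1.12) and Pcna (-0.75 to -0.68) changed little. With smaller fold changes and similar errors, calls ended for Top2a (log2 fold change -0.78, SE 0.10, to -0.31, SE 0.10, adjusted p = 0.0534) and Rpl14 (-0.69, SE 0.11, to -0.23, SE 0.10, adjusted p = 0.157). Hmgn5 (-2.10 to -0.59), Zc3h13 (-2.04 to -1.14), Ndc80 (-1.48 to -0.74), Hsp90aa1 (-1.35 to -0.87), Gbp8 (-1.06 to -0.67) and Casp8 (-0.59 to -0.35) stayed lower with smaller changes. Lag3 (0.95 to 0.61), Cox8a (0.94 to 0.50), Cxcr4 (0.68 to 0.35) and Izumo1r (0.66 to 0.35) stayed higher with smaller changes. With 1 library left out, the lone library of a group is assumed to vary like the other groups: 1920 genes changed without HD replicate 1 and 1549 without HD replicate 2.

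**Figure D4:**
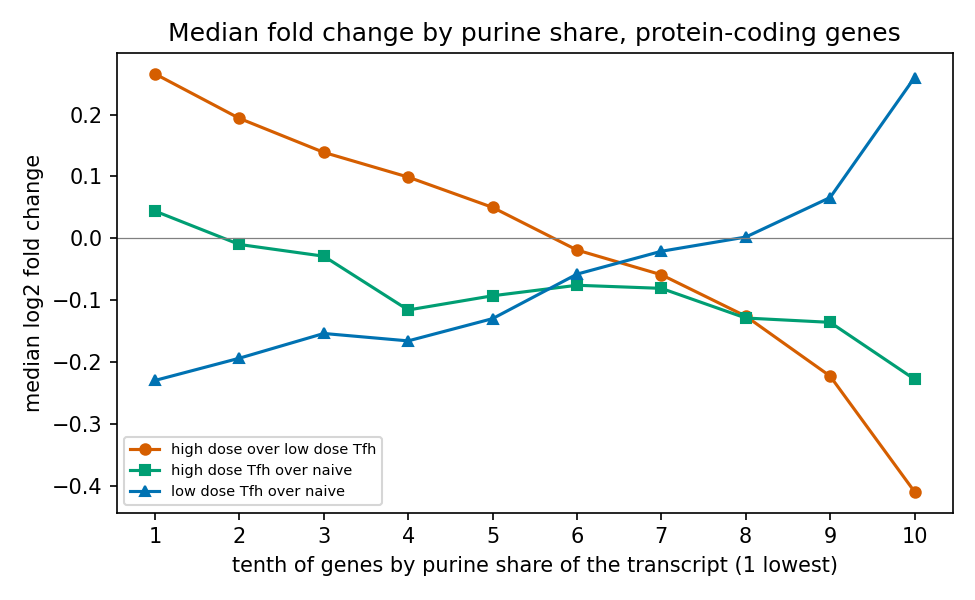
Median log2 fold change (vertical axis) of genes labelled protein coding in 10 classes of equal size by purine share of the transcript (horizontal axis), for the 3 comparisons. For HD over LD the medians ran from 0.266 in the lowest class to -0.41 in the highest.

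The comparison of HD Tfh with naive cells sets the sorted Tfh libraries of acute infection beside resting CD4 cells. The sort was visible in the counts: Cxcr5, the receptor that leads cells into follicles, stood at 622 ± 84.0 against 11.5 ± 1.85 CPM (log2 fold change 5.76, SE 0.17, adjusted p = 3.66e-10), and PD-1 (Pdcd1) at 185 ± 11.8 against 11 ± 1.18 CPM (4.07, SE 0.13, adjusted p = 5.02e-10). Tigit, an inhibitory receptor, stood at 306 ± 13.9 against 0.348 ± 0.102 CPM (9.78) and Maf, a Tfh transcription factor, at 504 ± 15.4 against 16.9 ± 1.99 CPM (4.90). Igfbp4, a gene of naive T cells, stood at 30.3 ± 0.0589 against 1757 ± 0.12 CPM (-5.86, SE 0.17, adjusted p = 5.82e-10). In all, 7292 of 14923 genes changed, 4105 higher and 3187 lower in the HD Tfh libraries. These libraries also held far more RNA of B cell and myeloid genes than naive cells, as given below. Which cells gave the rises in this comparison, on the gene lists or among the largest, was not tested.

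Of the 9 sort genes 5 rose and 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.111, fry adjusted p = 0.0241). With camera it was 0.033 without X, Y, immunoglobulin and other cell genes, and 0.00939 with the replicate number as a block. Cd44 (2.32) rose and Ly6c1 (-4.28) and Selplg (-1.34), which encodes CD162, fell. Ly6c2, a close paralog of Ly6c1, rose (3.05), and this call ended without naive replicate 1 (adjusted p = 0.0849) or replicate 2 (adjusted p = 0.0917). Of 30 Tfh genes 27 rose and 1 fell, likewise adjusted over the list alone (median 2.55; camera adjusted p = 1.4e-43, and adjusted p = 0.0934 with an estimated correlation). Bcl6 rose (120 ± 2.03 against 33.4 ± 8.48 CPM, 1.84), as did Il21, the cytokine of Tfh help (99.7 ± 25.9 against 0.658 ± 0.117 CPM, 7.24). Il4 was at least 159-fold higher against 0 naive counts, and Ifng stood at 55.3 ± 12.9 CPM against 2 counts in all in naive cells. Of 24 naive and resting genes 20 fell and 0 rose, likewise adjusted over the list alone (median -1.74; camera adjusted p = 7.33e-22, and adjusted p = 0.102 with an estimated correlation).

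Most measured genes of the Th1, Th2, Th17 and regulatory T cell lists rose in HD Tfh cells. Tbx21 stood at 46.0 ± 1.0 against 0.50 ± 0.00863 CPM (6.52), while Gata3 did not pass (55.5 ± 5.15 against 65.0 ± 3.14 CPM, -0.23). Of 28 Th1 genes 21 rose and 3 fell (23 and 3 adjusted over the list alone, camera adjusted p = 9e-17, and adjusted p = 0.146 with an estimated correlation), including the chemokine receptor Cxcr3 (382 ± 18.9 against 0.918 ± 0.0291 CPM, 8.70). Of 16 Th2 genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 5.36, or 3.46 with genes at their bound, camera adjusted p = 7.75e-05, and adjusted p = 0.254 with an estimated correlation). Of 13 Th17 genes 11 rose, likewise adjusted over the list alone (median 4.48, or 4.09 with bounds, camera adjusted p = 4.75e-07, and adjusted p = 0.228 with an estimated correlation). Of 17 regulatory T cell genes 12 rose and 2 fell (13 and 3 adjusted over the list alone, camera adjusted p = 1.31e-07, and adjusted p = 0.18 with an estimated correlation), with Ctla4 higher (3.87) and Foxp3 lower (1.15 ± 0.00084 against 3.45 ± 1.49 CPM, -1.58, and adjusted p = 0.16 without naive replicate 2, 0.0584 without HD replicate 1 and 0.0579 without HD replicate 2). Of 20 inhibitory and chronic stimulation genes 13 rose, likewise adjusted over the list alone (camera adjusted p = 2.01e-14, and adjusted p = 0.102 with an estimated correlation), with Lag3 at 5.57. Of 28 homing genes 17 rose and 6 fell (18 and 7 adjusted over the list alone; median 2.32, or 2.21 with bounds, camera adjusted p = 7.04e-06, and adjusted p = 0.0934 with an estimated correlation).

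Of 35 G2 and mitosis genes 34 rose, likewise adjusted over the list alone (median 4.62; camera adjusted p = 3.25e-49, and adjusted p = 0.0934 with an estimated correlation), and of 37 replication genes 34 rose and 1 fell, likewise adjusted over the list alone (median 1.98; camera adjusted p = 6.41e-20, and adjusted p = 0.162 with an estimated correlation). Top2a, the topoisomerase of dividing cells, stood at 98.0 ± 0.0395 against 8.09 ± 0.607 CPM. Of 20 glycolysis genes 14 rose (15 adjusted over the list alone, camera adjusted p = 7.51e-07, and adjusted p = 0.199 with an estimated correlation), with the lactate transporter Slc16a3 at 4.47. Of 61 ribosomal protein genes 49 fell and 0 rose (51 and 1 adjusted over the list alone; median -0.71; camera adjusted p = 6.2e-12, and adjusted p = 0.264 with an estimated correlation). Of 34 heat shock and immediate early genes 12 fell and 9 rose, likewise adjusted over the list alone (camera adjusted p = 0.00718, and adjusted p = 0.254 with an estimated correlation), and here camera pointed lower while median and mean were 0.04 and 0.03. This call ended without HD replicate 1 (adjusted p = 0.101) and without HD replicate 2 (adjusted p = 0.15). The chaperone Hsph1 stood at 53.3 ± 4.60 against 667 ± 10.3 CPM (-3.65). Of 21 apoptosis genes 11 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.156 with an estimated correlation; 0.0949 without HD replicate 1 and 0.0778 without HD replicate 2), with the BH3-only death gene Bbc3 at -3.54. Of 35 interferon gamma genes 18 rose and 5 fell, likewise adjusted over the list alone (camera adjusted p = 0.00853, and adjusted p = 0.587 with an estimated correlation; 0.101 without HD replicate 1).

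Genes of B lineage and myeloid cells were higher than in naive cells as well. All 20 B cell genes rose (median 5.23; camera adjusted p = 1.15e-39, and adjusted p = 0.0934 with an estimated correlation), as did 13 of 14 germinal centre and plasma cell genes (5.13; camera adjusted p = 1.13e-10, and adjusted p = 0.102 with an estimated correlation) and all 24 myeloid genes (5.25, or 5.09 with bounds, camera adjusted p = 4.8e-12, and adjusted p = 0.118 with an estimated correlation), the same counts adjusted over each list alone. Of 15 CD8 and natural killer genes 10 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.156 with an estimated correlation), with the pore-forming gene Prf1 lower (10.7 ± 0.506 against 148 ± 0.384 CPM, -3.79). Camera did not call type I interferon (14 of 40 higher, 10 lower), mitochondrially encoded (2 of 13 higher), respiratory chain (6 of 55 higher, 6 lower), cholesterol synthesis (7 of 23 higher, 1 lower), stromal (4 of 8 higher, fry adjusted p = 0.0369) or red cell genes (2 of 7 higher), where adjusted over the list alone these were 14 and 10, 0, 4 and 0, 7 and 1, 5, and 2. For the respiratory chain list, the test pointed lower with a median and mean above 0.

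**Figure D5:**
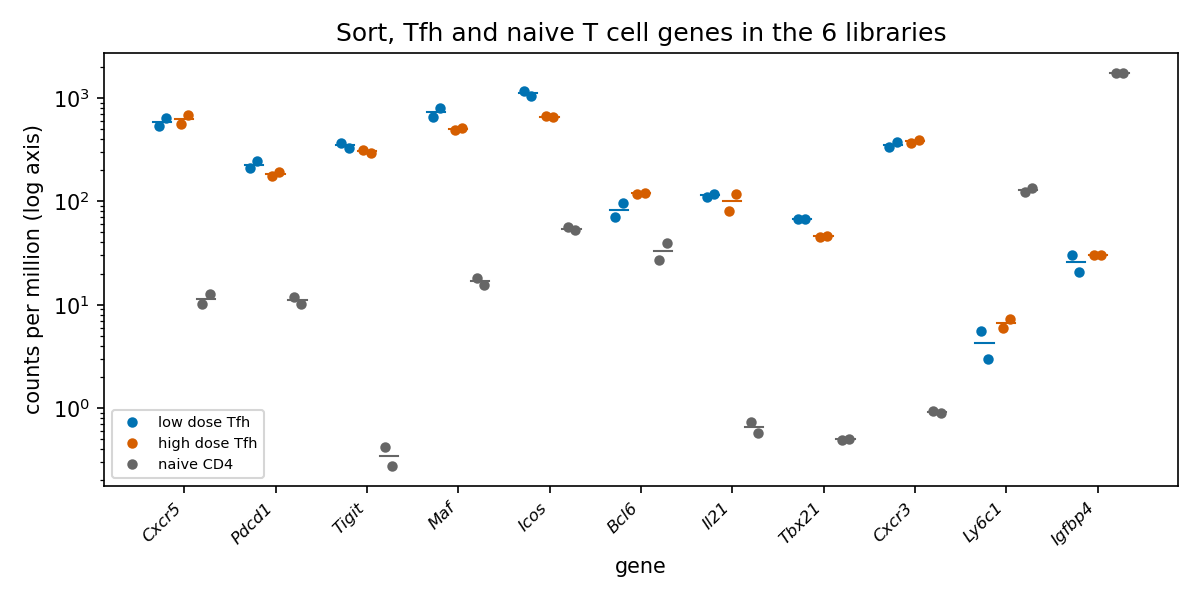
Level of 11 sort, Tfh and naive T cell genes in each of the 6 libraries, in CPM on a log axis, by group; dots are libraries and short lines group means of 2. Cxcr5 lay at 622 and 586 CPM in HD and LD Tfh cells and 11.5 CPM in naive cells, and Igfbp4 at 30.3, 25.7 and 1757 CPM.

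Under the naming rule the largest rises in HD Tfh over naive cells were Cxcl9 (at least 523-fold against 0 counts), Ifitm2 (411-fold), Ryr1 (397-fold), Bace2 (341-fold), Mnda (336-fold), Rab39b (300-fold) and Lpar3 (294-fold), each a lower bound. Esm1 (56.1 ± 9.48 CPM), Dnase1l3 (54.6 ± 9.91 CPM) and Sostdc1 (91.6 ± 12.2 CPM) had 1, 1 and 2 naive counts. The largest falls were Vwce (at least 347-fold lower), Ampd1 (-7.10), Dapk1 (-5.73), Apol9a (-5.37), Pdlim4 (-5.26), Sorcs2 (-5.26), Tbc1d16 (-4.92), Lbp (-4.89) and Tspan9 (-4.54).

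The comparison of LD Tfh with naive cells sets Tfh cells of chronic infection beside the same naive libraries. Unlike the HD and naive libraries, the LD libraries held Xist and no counts of the 4 Y-linked genes. Sex may therefore differ in this comparison, and its effects were not tested. Cxcr5 stood at 586 ± 74.9 against 11.5 ± 1.85 CPM (log2 fold change 5.67, SE 0.17, adjusted p = 4e-10), PD-1 (Pdcd1) at 226 ± 24.5 against 11 ± 1.18 CPM (4.36, SE 0.14, adjusted p = 4e-10) and Icos at 1105 ± 94.8 against 54.5 ± 2.59 CPM (4.34). The mitotic cyclin Ccna2 stood at 85.8 ± 15.2 against 0.314 ± 0.184 CPM (8.10). Igfbp4 stood at 25.7 ± 6.79 against 1757 ± 0.12 CPM (-6.09). In all, 6989 of 14923 genes changed, 3755 higher and 3234 lower in LD Tfh cells.

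Of the 9 sort genes 5 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.153, fry adjusted p = 0.027). Ly6c2 (2.31, and 1.38 without LD replicate 1) lost its call without naive replicate 1 (adjusted p = 0.139) or replicate 2 (adjusted p = 0.154). Of 30 Tfh genes 27 rose and 2 fell, likewise adjusted over the list alone (median 2.32; camera adjusted p = 2.27e-40, and adjusted p = 0.0868 with an estimated correlation). Il21 stood at 114 ± 5.25 against 0.658 ± 0.117 CPM (7.44), Bcl6 at 83.1 ± 17.7 against 33.4 ± 8.48 CPM (1.31), and Il4 was at least 135-fold higher. Of 24 naive and resting genes 21 fell, likewise adjusted over the list alone (median -1.63; camera adjusted p = 7.2e-24, and adjusted p = 0.13 with an estimated correlation). Of 28 Th1 genes 20 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 7.01e-20, and adjusted p = 0.146 with an estimated correlation), with Tbx21 at 7.06. Of 16 Th2 genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; median 5.59, or 3.68 with bounds, camera adjusted p = 3.06e-05, and adjusted p = 0.354 with an estimated correlation), with Il1rl1 at 8.69 and Gata3 not past the threshold (0.22, but 0.36 without LD replicate 1, adjusted p = 0.0484, and 0.44 after the purine correction, adjusted p = 0.0143). Of 13 Th17 genes 11 rose, likewise adjusted over the list alone (median 3.61, or 3.32 with bounds, camera adjusted p = 1.71e-05, and adjusted p = 0.378 with an estimated correlation). Of 17 regulatory T cell genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 9.7e-09, and adjusted p = 0.203 with an estimated correlation). Of 20 inhibitory genes 13 rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 2.66e-12, and adjusted p = 0.146 with an estimated correlation). Of 28 homing genes 16 rose and 8 fell (17 and 8 adjusted over the list alone, camera adjusted p = 0.000117, and adjusted p = 0.13 with an estimated correlation). This call ended without HD replicate 1, without HD replicate 2 and with the replicate number as a block (camera adjusted p = 0.134).

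All 35 G2 and mitosis genes rose (median 5.43; camera adjusted p = 3.16e-76, and adjusted p = 0.0868 with an estimated correlation), and 35 of 37 replication genes rose (2.16; camera adjusted p = 4.35e-34, and adjusted p = 0.146 with an estimated correlation), the same counts adjusted over each list alone. Of 40 type I interferon genes 23 rose and 7 fell (25 and 7 adjusted over the list alone, camera adjusted p = 0.0366, and adjusted p = 0.801 with an estimated correlation), including Oas1a (92.9 ± 0.386 against 28.8 ± 2.69 CPM, 1.69). This call ended without LD replicate 1 (adjusted p = 0.118), over genes labelled protein coding (0.0633), after the corrections for purines (0.0548) and for GC and length (0.0511), and with fry (0.12). Of 35 interferon gamma genes 17 rose and 5 fell (17 and 7 adjusted over the list alone, camera adjusted p = 0.0241, and adjusted p = 0.711 with an estimated correlation; 0.0841 without HD replicate 1, 0.0991 without HD replicate 2 and 0.0659 with fry). Of 61 ribosomal protein genes 39 fell and 1 rose, likewise adjusted over the list alone (median -0.58; camera adjusted p = 5.66e-10, and adjusted p = 0.378 with an estimated correlation). Of 20 glycolysis genes 14 rose (14 and 1 lower adjusted over the list alone, camera adjusted p = 1.07e-07, and adjusted p = 0.203 with an estimated correlation). Of 21 apoptosis genes 11 rose and 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.146 with an estimated correlation). The apoptosis call ended without HD replicate 1, without HD replicate 2 and with the replicate number as a block (camera adjusted p = 0.0533).

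Of 7 red cell genes 5 fell, likewise adjusted over the list alone (median -8.78, or -5.92 with bounds, camera adjusted p = 0.00505, and adjusted p = 0.378 with an estimated correlation). Camera did not call the B cell list, where 3 of 20 genes rose, including Cd22 (4.22), and 7 fell, including Spib (-2.39), nor the germinal centre (7 of 14 higher), myeloid (6 of 24 higher, 2 lower), CD8 and natural killer (6 of 15 higher, 4 lower) or stromal lists (3 of 8 higher). Adjusted over the list alone these were 3 and 8, 7, 6 and 2, 7 and 4, and 3. The B cell list was called lower without LD replicate 1 (adjusted p = 0.00898), and the germinal centre list higher without LD replicate 1 (adjusted p = 0.0367) or replicate 2 (adjusted p = 0.0444), with no filter (adjusted p = 0.0248) or with fry (adjusted p = 0.00484). Heat shock and immediate early genes (11 of 34 higher, 14 lower), mitochondrially encoded (4 of 13 higher), respiratory chain (11 of 55 higher, 12 lower) and cholesterol synthesis genes (9 of 23 higher, 1 lower) were not called, with the same counts adjusted over each list alone. Without LD replicate 1 the heat shock list was called lower (adjusted p = 0.042) and the cholesterol list higher (adjusted p = 0.00574). For the heat shock and myeloid lists, median, mean and test differed in sign.

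Under the naming rule the largest rises in LD Tfh over naive cells were Xist (at least 2388-fold), Mnda (727-fold), Acta2 (555-fold), Lpar3 (362-fold), Fads2 (351-fold), Ryr1 (348-fold), Dclk1 (346-fold) and Serpina9 (335-fold), lower bounds against 0 naive counts. Esm1 (63.2 ± 32.8 CPM) and Ifng (69.3 ± 39.0 CPM) had 1 and 2 naive counts. The largest falls were the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (at least 1679-, 1138-, 1100- and 708-fold lower), Hbb-bs (at least 317-fold lower), Vwce (at least 262-fold lower) and Pdlim4 (-7.10). Dapk1 and Hba-a1, at 11.5 ± 2.57 and 14.3 ± 12.6 CPM in naive cells, had 3 and 2 counts in LD Tfh cells. Hbb-bs and Hba-a1 lost their calls without LD replicate 1 (adjusted p = 0.143 and 0.143) or LD replicate 2 (0.139 and 0.13), and Hbb-bs without HD replicate 1 (0.15) or HD replicate 2 (0.145). Hbb-bs also lost its call with no filter (adjusted p = 0.129), only these 2 groups (0.0588) or thinned counts (0.0513).

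Both comparisons with naive cells called 2737 genes higher and 2216 lower, 4953 in the same direction, and 139 in opposite directions. Lists drawn independently would share 1033, 691 and 1692. In 20 simulations of unchanged groups that shared the naive libraries, a mean of 0.05 genes was higher in both, and 0 were lower in both. These simulations held no real effects and a split would leave each comparison 1 naive library, so part of the excess of these counts over independent lists may come from the shared controls. Across 8429 genes with a mean of at least 10 CPM, the covariance of the 2 log2 fold changes was 1.20 against a simulated 0.0126, a difference of 1.19 (genes are not independent replicates). Of the 4953 genes, 962 also differed between HD and LD Tfh cells, 511 higher and 451 lower in HD.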

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

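The tests of explanations in this part were chosen only after the results had been seen, while the gene tests behind the counts of opposite changes were planned. Between the comparisons with naive cells, 82 genes were higher in HD and lower in LD Tfh cells, and 57 were lower in HD and higher in LD, each with a difference between HD and LD that passed edgeR's test. Of the 82, 12 are immunoglobulin genes, 10 are on the lists of other cell types and 3 lie on X or Y, and of the 57, 0, 0 and 3. The lists hold only some genes of each cell type, so more genes of such cells may be among the 82. In all, 57 of the 82 were at least 4-fold higher in HD than in LD. The 82 include the B cell genes Ms4a1 (log2 fold changes of 5.45 and -0.39) and Spib (5.56 and -2.39), and Psap (0.28 and -0.82) and Cox8a (0.58 and -0.36). Those lower in HD and higher in LD include Vim (-0.28 and 1.01), Smc4 (-0.80 and 0.80) and Usp18 (-0.41 and 0.33). Of these, Psap, Vim and Smc4 were chosen after their values were seen. The trend with purine share also ran in opposite directions against naive cells (Spearman's correlation across genes -0.11 for HD and 0.198 for LD). Whether the 82 and the 57 genes keep their opposite changes after the purine correction was not tested.

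B lineage and myeloid genes were higher in HD than in LD Tfh libraries, where 50 of 58 measured members of the 3 lists for B cells, germinal centre B and plasma cells and myeloid cells were called higher, with their abundant genes Cd74 at 2080 and 1740 CPM and Lyz2 at 59.4 and 75 CPM in HD. Against deeper sequencing of the HD libraries, all 50 members stayed called after thinning. RNA of B lineage and myeloid cells in the HD libraries may account for the pattern, although the sort on CD4, PD-1 and CXCR5 should remove such cells when single, and the count of 50 restates it and decides nothing. The HD library with the fewest held 80 heavy chain variable genes with at least 10 counts, where no LD or naive library held over 3. This count alone does not tell such RNA from expression by the Tfh cells themselves. Expression of immunoglobulin genes by Tfh cells would not account for the 20 of 24 myeloid genes that also rose. Of the 58 members, 22 lay at 1 CPM or more in LD and 25 in naive cells, 1 is on another list, and a difference in Tfh cells between acute and chronic infection stays open, untested.

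The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both LD libraries and Xist was high there, while the labels do not give the sex of the mice. Against a single mislabelled library, 0 of the 3 groups had libraries that differed in this pattern. Of the HD against LD calls, 3.54% lay on X or Y, where 3.55% of the tested genes lie. Only 530 tested genes lie there, so they could not have made up most of the 3276 calls. This share therefore decides nothing about sex as a source of the calls. All 6 libraries showed either Xist with no Y-linked counts or the reverse with at most 10 counts of Xist, which largely restates the pattern. LD mice of another sex than the HD and naive mice may account for it. Sex would then go with egg dose. It would also differ between LD and naive cells but not between HD and naive cells, which bears on the overlap and the opposite changes above. Effects of sex on autosomal genes were not tested.

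The HD against LD fold change fell with the purine share of the transcript. Against GC content, the rank correlation across genes was -0.497 given GC content. A sequence-dependent step of library making may contribute, since the purine share of the 3' untranslated region, given that of the coding part, still went with the fold change (-0.188 across 6474 genes), and since replicates of a group differed in the trend (0.227 for HD replicate 1 minus 2, 0.0371 for LD and 0.0753 for naive). The coding part given the 3' untranslated region went with it more strongly (-0.479 across the same genes), and across 369 non-coding RNAs the correlation was -0.16 (95% bootstrap interval over genes -0.261 to -0.0558), so a programme of proteins with purine-rich codons stays open. No label gives library batches, so such a step and the infection groups cannot be told apart as the source, and a biological difference in RNA turnover between acute and chronic infection stays open, untested.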

How the results depend on the processing

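The corrections for purine share and for GC content and length, the thinned counts, the run of genes labelled protein coding and the run without X, Y, immunoglobulin and other cell genes were chosen only after the results had been seen; the other alternatives were planned. Across the 12 alternatives that keep all libraries, the genes changed ran from 2444 to 3913 for HD against LD, 5919 to 7565 for HD against naive and 5621 to 7286 for LD against naive, each within 1.5 times the value reported. The overlap ran from 3445 to 5040 over 3 alternatives, with 3445 at an adjusted p under 0.01. With a library left out the lone library of its group is assumed to vary like the other groups. The genes changed then ran from 1549 to 3183, 5519 to 7672 and 5565 to 6577, where 1920 genes changed for HD against LD without HD replicate 1 and 1549 without HD replicate 2, and the lists called ran from 8 to 11, 16 to 20 and 13 to 19.

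With an estimated correlation camera called 1, 0 and 0 lists in place of 9, 19 and 16. For HD against LD the estimates included 0.212 for G2 and mitosis, 0.427 for replication and 0.587 for type I interferon, against the preset 0.01. At an estimate of 0.00121 the homing list of HD against naive also lost its call, so a high estimate is not the sole cause. Without X, Y, immunoglobulin and other cell genes camera called 4 of the 20 lists left for HD against LD, all lower, since the 5 higher lists were taken out. The cholesterol synthesis list of HD against LD turned from lower, not called, to higher (adjusted p = 0.0383) without LD replicate 2, and was called lower without LD replicate 1 (adjusted p = 0.0288). Its adjusted p ran from 0.0288 to 0.735 with a library left out, and the cause was not tested. Without LD replicate 1 the Th17 (adjusted p = 0.0162) and inhibitory lists (0.0138) were called higher, without LD replicate 2 the Th1 list lower (0.0218), without HD replicate 1 the Tfh list higher (0.0306), and without naive replicate 1 the red cell list of HD against naive higher (0.0129). After the purine correction Atp5h of the respiratory chain turned from -0.59 to 0.28 (adjusted p = 0.13), 14 other named genes lost their calls, and the mitochondrially encoded list was called lower (adjusted p = 1.9e-05). Over all 6769 pairs of a named gene and an alternative, 135 lost and 59 gained a call, and 1 with a call changed sign. Changes of sign in genes called in neither fit, such as Ifng, were not counted.

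With the replicate number as a block, 3176, 7154 and 6797 genes and 9, 20 and 14 lists were called. The pairing was not borne out: deviations of libraries with the same number correlated across genes at 0.18 for LD and HD, -0.126 for LD and naive and 0.0862 for HD and naive. At these depths 2-fold changes of genes at 10 CPM or more were recovered in simulation. Changed genes under 10 CPM and changes under 2-fold were not simulated. With 2 libraries a group, genes near 1 CPM and changes under 2-fold are the least secure.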

Other observations

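The genes and comparisons in this part were chosen only after their values had been seen. Il18r1 (chromosome 1, 40465552 to 40500854, GRCm38) lies between Il1rl1 and Il18rap, and all 3 were lower in HD than in LD Tfh cells, with log2 fold changes of -1.79, -1.75 and -1.03. The call of Il18rap ended without HD replicate 1 (log2 fold change -0.987) and without HD replicate 2 (-1.065). Its log2 fold change was -0.632 without LD replicate 1. Their neighbours Il1r2 (0.81), Il1r1 (0.20), Il1rl2 (0.32) and Mfsd9 (1.46) did not pass. Against naive cells Il18r1 was higher in LD (2.10, adjusted p = 7.63e-06) and did not pass in HD (0.31, adjusted p = 0.182), while Il18rap was higher in both LD (6.32) and HD (5.28).

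T cell receptor variable gene usage stayed broad in all 6 libraries. The effective number of Trbv genes (the inverse of the summed squared shares) was 13.6 and 12.9 in LD, 14.3 and 13.6 in HD, and 13 and 13.4 in naive libraries. Trbv13-2 took 14.8% and 16.4% of Trbv counts in LD, 11.7% and 10.8% in HD, and 10.7% and 10.9% in naive libraries. Of 95 alpha and beta variable genes tested, 2 were higher and 2 lower in HD than in LD, 0 and 10 in HD against naive, and 2 and 11 in LD against naive.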
